A study of Mus musculus with 6 samples.

How the data were processed

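RNA-seq libraries of mouse liver were compared between 3 libraries labelled wild type and 3 labelled hepatocyte-specific HIF-2α knockout, all from mice on a high-fat diet for 16 weeks. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an NEB kit. The authors deposited one table of TPM (transcript abundance corrected for length and scaled to one total per library) for 54600 genes and 6 libraries, given to 3 decimals, in which every column sums to the same total. Per the submitters' processing notes, fastp, HISAT2, featureCounts, DESeq2 and limma were used with the mm10 build, with no versions, roles or order given. TPM values keep no sequencing depth, so a count model was not used, no counting interval is given, and an exact 0 is reported only as listed at 0. The counting mode (strand, shared reads) is not given in the sources used here, so values of pseudogenes, of close paralogs such as the Mup and Mug genes, and of overlapping genes such as mt-Atp8 and mt-Atp6 are uncertain.

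Of the identifiers, 50763 are Ensembl genes, 3560 join an assembled locus to an Ensembl gene and 277 are assembled loci alone, and the tool that assembled them is not given in the sources used here. Of 54323 Ensembl identifiers, 51492 matched a gene name in GENCODE M21, which is on the same build as mm10 and gave the coordinates. Where a symbol had several identifiers, lists used the one with the highest mean TPM.

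Genes with at least 1 TPM in at least 3 of the 6 libraries were tested (11440) with limma 3.58.1 in R 4.3.3, on log2(TPM + 1), with a variance trend, two-sided, and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. A total of 47 gene lists on metabolism, hypoxia, inflammation, fibrosis, cell types and technical signs was fixed, and 42 had at least 5 tested members. The lists were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 42 lists. The neutrophil, T and NK cell, B and plasma cell, muscle and pancreas, and mesothelial and gallbladder lists had 2, 3, 4, 2 and 0 tested members and were not tested. On simulated data with 200 of 11440 genes changed, the limma step recovered 16%, 64%, 86% and 96% of genes changed 1.5-, 2-, 3- and 4-fold (50 genes each), with 7 false calls among 11240 unchanged genes and 0 calls when none was changed. The simulated genes varied independently of each other, and the changed genes were drawn from those with a mean of at least 5 TPM.

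The genes named are Epas1; genes past the threshold with separated groups and a mean of at least 5 TPM, up to 12 per direction and no predicted genes (0 qualified); up to 4 members with the smallest p of each called list and of the lists on lipids, HIF, fibrosis and inflammation; and, where fewer than 5 genes passed in a direction, the 10 genes with the smallest p in that direction with a mean of at least 5 TPM, as values with no call. The lists, the design and the first set of alternatives were fixed before the data were examined. Gm13597 and the genes of the closing section that fall outside this rule were chosen after their values were seen.

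The libraries were compared before averaging. Spearman correlations between libraries lay between 0.945 and 0.978, and no pair shared more than 0.157% of exact values, so each was used as 1 replicate. The labels give the numbers 1 to 3 in both groups without saying that they pair the animals. The deviations of same-numbered libraries from their group means were correlated at 0.16, 0.41 and 0.38, each above 0.1, and those of differently numbered ones at -0.37 to 0.03. The numbers were therefore treated as a possible pairing of the libraries, from the data and not from the labels. No test against other ways of matching the libraries was run, and deviations within a group sum to 0, so the pairing is not established. The fit without the block was fixed as the main one, and the fit with the replicate number as a block was an alternative.

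Alternatives fixed with the design were a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, median-ratio scaling, quantile normalization, TPM recomputed without the 20 most abundant and the mitochondrial genes, no variance trend, a robust trend, the replicate block, library weights, an estimated correlation for lists, and leaving out each library in turn. Leaving out both libraries of 1 number, and the block with median-ratio scaling, were added after seeing the data. For called lists the alternatives were first to be compared by mean log2 difference, and the adjusted p was compared in its place after seeing the data. Transcript sequences were matched with BLAST 2.17.0.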

Results

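RNA was sequenced from the livers of mice fed a high-fat diet for 16 weeks. The libraries fall into 2 groups of 3, labelled wild type (WT) and hepatocyte-specific knockout of HIF-2α (KO). HIF-2α, encoded by Epas1, is the oxygen-regulated subunit of a hypoxia-inducible transcription factor. All 6 libraries came from animals on this diet, so the comparison addresses how the liver transcriptome on this diet differed with the genotype label. The labels number the libraries 1 to 3 in each group and do not say that each came from a separate animal, so the limma p-values measure the spread between these samples. Those of camera at its preset correlation rest mainly on the spread between genes. Expression was given as TPM, transcript abundance corrected for length and scaled to the same total in every library, and sequencing depth is unknown because TPM keeps no read totals. Between 11013 and 11708 genes reached 1 TPM in a library, and 11440 genes were tested. The 20 most abundant genes took between 40.7% and 46.8% of the TPM of a library.

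The targeted gene was not lower in the libraries labelled KO. Epas1 (MSTRG.1523|ENSMUSG00000024140; mm10 chromosome 17, 86753700 to 86833410, plus strand) was at 23.8, 26.0 and 21.0 TPM in the libraries labelled WT and at 26.6, 35.1 and 29.4 TPM in those labelled KO. The means were 23.6 ± 2.52 and 30.4 ± 4.31 TPM (SD, n = 3 each), a difference of +0.34 on the log2(TPM + 1) scale with a standard error of 0.15. The limma p was 0.050 unadjusted and 0.993 adjusted over all tested genes. With the replicate number as a block, the unadjusted limma p was 0.017. The limma confidence interval of the difference, at the level used for Vegfa below, ran from -4.1e-05 to +0.69. Median-ratio scaling brought the difference to +0.23. An exact two-sided permutation test gave p = 0.10, the smallest that 3 libraries against 3 allow. Its longest coding transcript in GENCODE M21 has 16 exons over 5516 bases, and the largest internal exon holds 9.17% of that length. The TPM values cover the whole gene and all cells of the liver, including those in which a hepatocyte-specific deletion leaves the gene intact. The labels could therefore not be checked from this gene, which went against them, and every direction given here is between the libraries labelled KO and those labelled WT.

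Across the transcriptome, 1 gene passed the threshold and it was lower in the libraries labelled KO, while no gene was higher (limma, Benjamini-Hochberg adjusted p below 0.05). That gene was Gm13597 (ENSMUSG00000075312; mm10 chromosome 2, 68554555 to 68554929), a processed pseudogene. It was at 3.45, 5.26 and 4.73 TPM in the libraries labelled WT and listed at 0 in all 3 labelled KO (limma adjusted p = 0.0173). All 375 bases of its transcript are identical to part of a transcript of Tax1bp3, so its reads cannot be told from those of that gene. It was chosen for mention after its values were seen. With the replicate number as a block, the alternative that treats same-numbered libraries as pairs, no gene passed in either direction and the adjusted p of Gm13597 was 0.171. Leaving out any 1 library also ended its call, with adjusted p of 0.0698, 0.0505 and 0.315 without WT replicate 1, 2 or 3 and 0.0733, 0.0552 and 0.0798 without KO replicate 1, 2 or 3. Over the alternatives run, the adjusted p of Gm13597 ran from 0.00911 to 0.9999. The next smallest adjusted p of any gene was 0.582.

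Before adjustment, 360 genes had a limma p below 0.05, which is 3.15% of those tested, with 316 higher and 44 lower in the libraries labelled KO. With the replicate block there were 707, with 602 higher and 105 lower, and the block with median-ratio scaling gave 227 higher and 289 lower. The direction of this split depended on the scaling: dividing the libraries by median ratios moved the median log2 difference of all genes by -0.11, from +0.09 to -0.01, and gave 139 higher and 162 lower. Quantile normalization gave 141 higher and 155 lower, and TPM recomputed without the most abundant and mitochondrial genes gave 258 higher and 114 lower. All 3 libraries of one label lay above all 3 of the other in 9.08% of genes. Chance gives 10% for 6 exchangeable libraries, which these may not be, given the correlation between same-numbered libraries, so the share was not read against it. Simulated data of this size had 200 genes changed, 50 at each fold. There the test recovered 64% of genes changed 2-fold and 86% of those changed 3-fold. Genes varied independently there and the changed ones had a mean of at least 5 TPM. These rates need not hold for lower genes or for libraries that vary together. They would also be lower with fewer genes changed, because the adjustment is then stricter. With 1 gene called here, they do not bound how many 2-fold or 3-fold changes were missed.

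None of the genes with the smallest p-values described next was called. Abca8a, a membrane transporter of the ABC family (chromosome 11, 110025634 to 110095978), was at 22.6 ± 1.13 TPM in the libraries labelled WT and 49.2 ± 7.71 in those labelled KO (SD, n = 3 each), with an adjusted p of 0.582 in limma. Mug2, one of several closely similar murinoglobulin genes, was at 95.6 ± 20.9 and 200.6 ± 34.6 TPM. Cln3, which encodes a lysosomal membrane protein, was at 5.88 ± 0.496 and 10.1 ± 0.405 TPM, and Gsn, encoding the actin-severing protein gelsolin, at 6.03 ± 1.38 and 12.8 ± 2.40. Malsu1 was at 5.67 and 11.97 TPM, Cnih4 at 5.70 and 9.22, Trmt2a at 4.30 and 7.68, and Gpank1 at 3.99 and 7.40. The unnamed assembled locus MSTRG.3786 was at 33.4 and 57.4 TPM, and the processed pseudogene Gm46223 at 29.0 ± 13.1 and 113.6 ± 56.7.

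In the other direction, Mvd, an enzyme of the mevalonate pathway (chromosome 8, 122433601 to 122443422), was at 9.15 ± 0.811 TPM in the libraries labelled WT and 5.64 ± 0.672 in those labelled KO. Oat, the ornithine aminotransferase of pericentral hepatocytes (chromosome 7, 132557478 to 132576398), was at 582 ± 63.1 and 399 ± 42.0 TPM. Insig1, which retains the SREBP regulators of sterol synthesis in the endoplasmic reticulum, was at 146 ± 22.8 and 103 ± 4.75 TPM, and Hmgcs1, the cytosolic HMG-CoA synthase, at 119.5 ± 12.7 and 91.2 ± 10.7. Nfe2l1, a transcription factor that regulates proteasome genes, was at 41.7 and 29.8 TPM, Dleu2 at 16.2 and 9.64, Gatb at 24.4 and 16.8, and A930005H10Rik at 11.2 and 7.85. The pseudogene Gm4963 was at 8.01 and 4.79 TPM. Eif4a-ps4 was at 19.3, 14.4 and 18.1 TPM in the libraries labelled WT and was listed at 0 in KO replicates 1 and 3, with 12.9 TPM in KO replicate 2. Without that library it passed the threshold (limma adjusted p = 0.00118), as it did without both libraries numbered 2 (0.00298), against 0.724 to 0.9999 under the other alternatives.

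**Figure D1:**
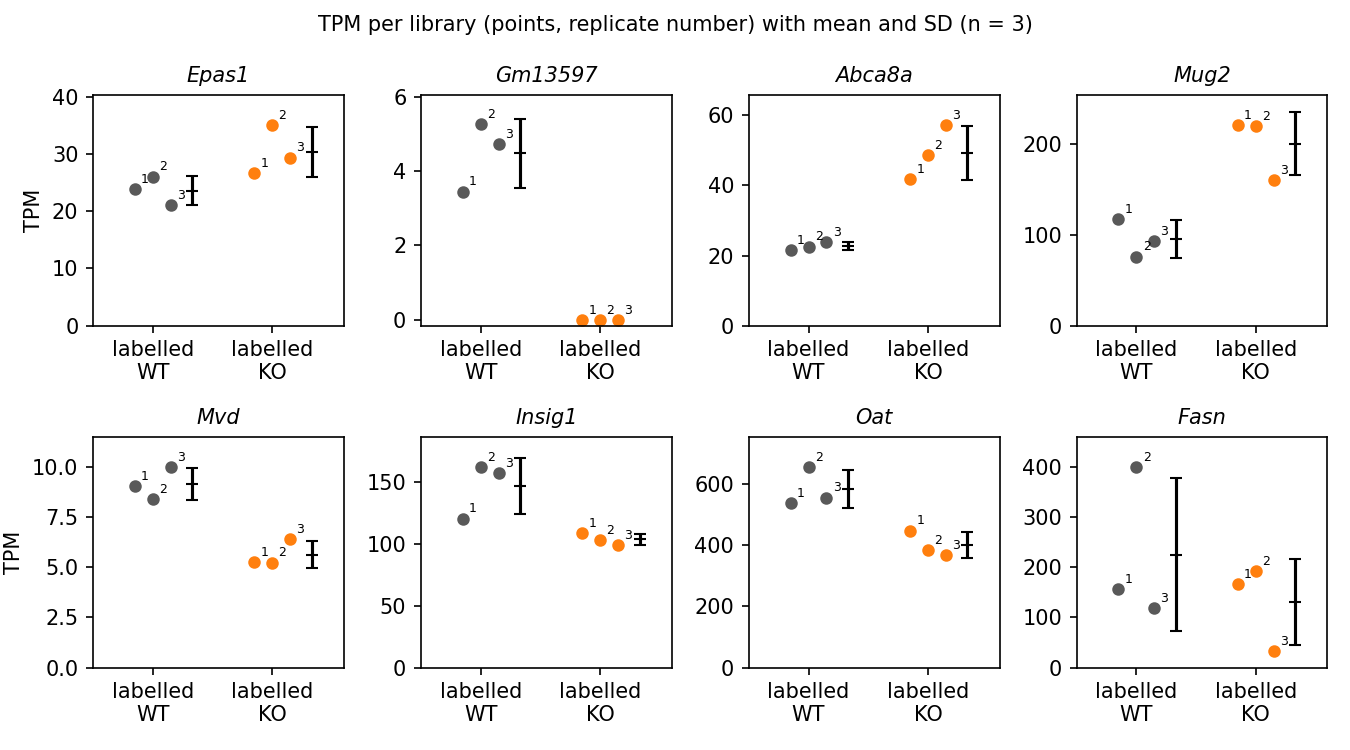
TPM of 8 genes in each library (points, numbered by replicate) with the mean and SD of each label (n = 3; none drawn for the libraries listed at 0), on linear axes. Epas1 lies between 21.0 and 26.0 TPM in the libraries labelled WT and between 26.6 and 35.1 in those labelled KO, and only Gm13597 of these genes passed the limma threshold.

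Genes of sterol synthesis were called lower as a group in the libraries labelled KO. A call by camera is relative to the other tested genes, whose median difference was +0.09, so a list called lower can have a mean near or above 0. Of 26 measured genes of cholesterol synthesis and SREBP2 targets, 24 had a log2 difference below 0 and the mean was -0.23 (camera, preset correlation, adjusted p = 7.3e-12; adjusted p = 0.902 with an estimated correlation, as for all 11 called lists). Mvd, Insig1 and Hmgcs1, with the values above, were the 3 members with an unadjusted p below 0.05, and Ggps1, which makes geranylgeranyl diphosphate, was at 4.28 and 5.90 TPM in the opposite direction. Fatty acid and triglyceride synthesis was also called lower, with 21 of 24 members below 0 and a mean of -0.28 (adjusted p = 3.2e-05). Its members varied widely between libraries of one label: Fasn, the fatty acid synthase, was at 157, 399 and 119 TPM in the libraries labelled WT and at 166, 192 and 32.98 in those labelled KO, and the glycerol acyltransferase gene Gpam at 118 ± 47.4 and 90.6 ± 37.4. The members with the smallest p-values, the desaturase gene Scd2 (1.08 and 1.65 TPM) and Mlxipl (28.2 and 36.1 TPM), which encodes the carbohydrate-responsive factor ChREBP, went the other way. The call on fatty acid synthesis was lost without WT replicate 2 (adjusted p = 0.403) and without KO replicate 3 (0.501). The per-library means of both lists overlapped between the labels (exact permutation p = 0.40 and 0.70), and the mean of the cholesterol list was higher in KO replicate 2 (0.35) than in WT replicate 2 (0.28).

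Pericentral hepatocyte genes, expressed around the central vein, were called lower, with 26 of 30 members below 0 and a mean of -0.16 (adjusted p = 5.4e-11). Besides Oat, the glutamate transporter gene Slc1a2 was at 48.9 ± 1.06 TPM in the libraries labelled WT and 40.3 ± 3.41 in those labelled KO, the Wnt pathway receptor gene Lgr5 at 1.78 and 1.23, and Lhpp at 33.7 and 27.0. The mean of the list was lower in the KO-labelled library of all 3 same-numbered pairs. Periportal genes were not called (adjusted p = 0.983). Xenobiotic metabolism and NRF2 target genes were called lower with means of -0.03 and -0.06 (adjusted p = 0.00295 each), which median-ratio scaling brought to -0.14 and -0.18. Gstm2, a glutathione transferase in both lists, was at 46.0 and 35.9 TPM, whereas Cyp2d22 was at 68.2 and 86.3 and Cyp3a11 at 144 ± 36.3 and 254 ± 122, in the opposite direction to the call. Without WT replicate 2 the adjusted p of the xenobiotic list was 0.846 and that of the NRF2 list 0.0946, and without KO replicate 3 they were 0.958 and 0.397. Without KO replicate 2 that of the NRF2 list was 0.126. Median-ratio scaling left the xenobiotic list at 0.0529, or at 0.00713 with the replicate block added. Quantile normalization left the xenobiotic and NRF2 lists at 0.168 and 0.0969. With no filter on low values they were at 0.273 and 0.171.

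The other 4 lists called lower also had small mean differences. Mitochondrially encoded genes had a mean of -0.07 (adjusted p = 0.00295), and mt-Nd3, a complex I subunit, was at 6706 ± 1689.9 and 5469 ± 676 TPM. This call was lost without WT replicate 2 (adjusted p = 0.337), WT replicate 3 (0.108), KO replicate 2 (0.0611) or KO replicate 3 (0.118), under quantile normalization (0.733) and with no filter on low values (0.216). Bile acid synthesis and transport (adjusted p = 0.0263) had a mean of -0.05 and a median of +0.02, and Nr0b2, the nuclear receptor SHP that represses bile acid synthesis, was at 22.7 ± 13.0 and 10.2 ± 5.12 TPM. Glycolysis and fructose metabolism (0.0331) had a mean of -0.02, with Aldoa at 44.8 and 52.0 TPM and Pfkl at 8.83 and 10.2. Male-biased liver genes were called lower (0.0487) although their mean was +0.02 and their median +0.04, and each other scaling turned the mean negative. The bile acid call was lost without WT replicate 3 (0.247), KO replicate 1 (0.212) or KO replicate 3 (0.124). The glycolysis call was lost without WT replicate 2 (0.587), and without KO replicate 3 its direction turned (0.857). The direction of the male-biased call turned without WT replicate 3 (0.0373), KO replicate 1 (0.913) or KO replicate 2 (0.981). The bile acid, glycolysis and male-biased lists also lost the call under each other scaling and with no filter (0.343, 0.273 and 0.343). With the replicate block added to median-ratio scaling, the bile acid and glycolysis lists kept it (0.00971 and 0.0169) and the male-biased list did not (0.156).

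Fibrosis and ribosomal protein genes were called higher in the libraries labelled KO. Of 30 stellate cell and fibrosis genes, 28 had a log2 difference above 0, with a mean of +0.20 (camera adjusted p = 0.00598), which median-ratio scaling and quantile normalization each brought to +0.10. Without such scaling their per-library means did not overlap between the labels (exact permutation p = 0.10, the smallest possible). The contractile genes Tagln and Acta2 were at 4.05 ± 0.777 and 1.27 ± 0.446 TPM in the libraries labelled WT and at 6.10 ± 0.744 and 2.23 ± 0.328 in those labelled KO. Lum, encoding the collagen-binding proteoglycan lumican, was at 3.56 and 4.74 TPM, and the collagen gene Col1a2 at 1.72 and 2.44. The call was lost without KO replicate 2 (adjusted p = 0.248). Without scaling, means of recruited macrophage and cholangiocyte markers also did not overlap, with differences of +0.27 and +0.21 that median-ratio scaling brought to +0.17 and +0.12, but neither list was called in the main fit (adjusted p = 0.221 and 0.738). Under the replicate block with median-ratio scaling the macrophage list was called higher (camera adjusted p = 0.0284). Of 47 ribosomal protein genes, 46 were above 0 with a mean of +0.12 (adjusted p = 4.6e-04), which median-ratio scaling brought to -0.002 (adjusted p = 0.109). Without scaling, the ribosomal and fibrosis means were higher in the KO-labelled library of all 3 same-numbered pairs. Rps16 was at 122 ± 9.24 and 148 ± 9.30 TPM.

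In all, 11 of 42 tested lists were called, 2 higher and 9 lower. Camera at its preset correlation of 0.01 treats the genes of a list as nearly independent. Estimated correlations of the called lists ran from 0.0214 (bile acid) to 0.698 (fatty acid synthesis), with 0.446 for cholesterol synthesis and 0.158 for pericentral genes. With an estimated correlation between genes no list was called (smallest adjusted p = 0.902), and fry, which asks whether a list moves on balance one way, called none (smallest adjusted p = 0.880). Exact permutation of the list means gave p = 0.30 for pericentral and 0.20 for ribosomal protein genes. No member of any list passed when adjusted over the list alone, and none passed over all genes tested. With the replicate block all 11 lists kept their call and 3 more were called higher, giving 5 higher and 9 lower. The added lists were the acute phase response (adjusted p = 0.0472), MHC class II antigen presentation (0.0114) and ER stress (0.0133), and with an estimated correlation the smallest adjusted p under the block was 0.730.

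**Figure D2:**
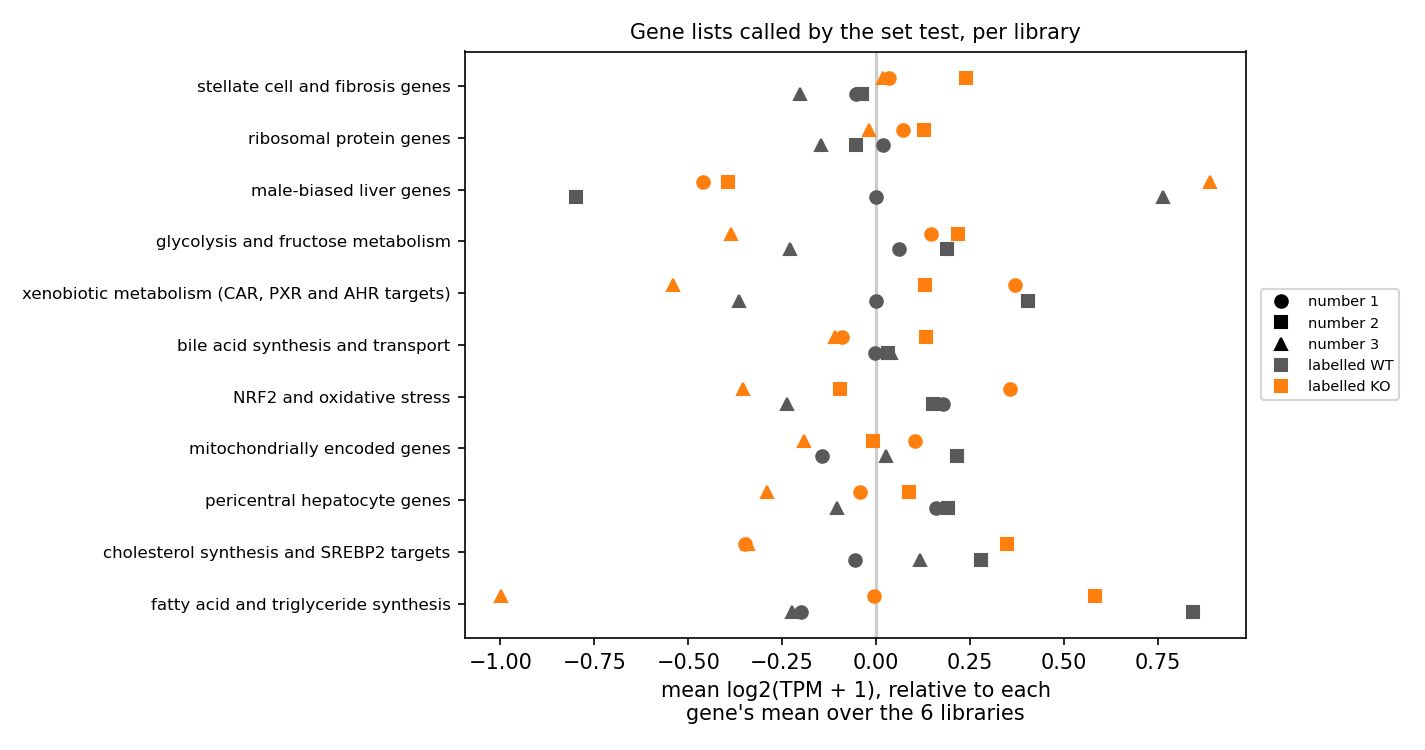
Mean log2(TPM + 1) of each called gene list in each library, relative to each gene's mean over the 6 libraries, with marker shape giving the replicate number and colour the label. For male-biased genes both libraries numbered 3 lie highest, at 0.76 (WT) and 0.89 (KO). Of the 11 lists only stellate cell and fibrosis genes have all 3 libraries of one label above all 3 of the other, without regard to the replicate number.

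None of the 3 lists on hypoxia signalling was called. The HIF pathway components had a mean of +0.10 (camera adjusted p = 0.911), general hypoxia targets +0.04 (0.438) and genes described as HIF-2 responsive in liver +0.02 (0.235), and median-ratio scaling turned all 3 means negative (-0.02, -0.07 and -0.08). Among HIF-2 responsive genes, the insulin receptor substrate gene Irs2 was at 1.99 ± 0.458 TPM in the libraries labelled WT and 3.29 ± 1.43 in those labelled KO, the lipid droplet gene Hilpda at 2.29 ± 0.332 and 1.81 ± 0.131, Vegfa at 33.6 ± 6.77 and 40.1 ± 11.2, and its receptor gene Flt1 at 2.23 and 2.49. The 95% interval of the Vegfa log2 difference ran from -0.34 to +0.79. Among general hypoxia targets, Ndrg1 was at 2.86 ± 0.178 and 4.53 ± 0.943 TPM and the histone demethylase gene Kdm3a at 3.25 ± 0.505 and 4.83 ± 0.749, while Ddit4, an inhibitor of mTORC1 signalling, was at 8.59 ± 3.81 and 4.76 ± 2.37. Rbx1, a subunit of the ubiquitin ligase that degrades HIF subunits, was at 24.96 ± 1.99 and 33.1 ± 5.04 TPM.

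Other lipid and inflammation lists were not called on all 6 libraries without the block or another scaling. For fatty acid oxidation the adjusted p was 0.224, for lipid uptake and droplets 0.397, for lipoproteins 0.738 and for ceramide metabolism 0.438. Fatty acid oxidation was called lower without WT replicate 3 (adjusted p = 0.00116) or KO replicate 1 (0.00190), and lipid uptake and droplets without KO replicate 1 (0.0127). Scarb1, the hepatic HDL receptor, was at 61.3 ± 5.99 and 81.5 ± 9.62 TPM, and Apoa1 at 6837 ± 336 and 8820.5 ± 1572. Of the fatty acid binding protein genes, Fabp4 was at 12.1 TPM in the libraries labelled WT and 15.3 in those labelled KO. Fabp5 was at 12.6 ± 7.61 and 35.0 ± 25.9 TPM and overlapped, with KO replicate 1 at 7.31, below WT replicates 2 and 3 (19.7 and 13.4). For the acute phase response the mean was +0.31 (adjusted p = 0.148), with the metallothionein genes Mt1 at 13.1 ± 9.18 and 35.9 ± 13.8 TPM and Mt2 at 6.54 ± 3.73 and 17.7 ± 7.27, Socs3 at 1.22 and 2.34, and Lbp at 24.5 and 41.1. The acute phase list was called higher under quantile normalization (adjusted p = 0.00511), without WT replicate 1 (0.000279) and without KO replicate 2 (0.00398). For cytokines and chemokines the adjusted p was 0.819, with Cxcl1 at 2.57 and 3.50 TPM and Ccl9 at 35.8 and 49.6, and for the interferon response it was 0.738, with Iigp1 at 150.1 and 178. The interferon list was called lower without WT replicate 2 (0.0174).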

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

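The alternatives that leave out both libraries of 1 number, and the replicate block with median-ratio scaling, were chosen after the data were seen, as was the comparison of lists by adjusted p. Epas1 stayed higher in the libraries labelled KO and uncalled under every alternative run (log2 difference from +0.23 to +0.44). Of 2056 values of 99 named genes under the alternatives, 2049 kept their sign. The exceptions were mt-Atp6 under quantile normalization (+0.21), Slc2a5 without KO replicate 2 (-0.0187, and up to +1.09 with another library left out), and mt-Atp8 without KO replicate 3 (+0.0192, and down to -0.33). With both libraries numbered 2 left out, the log2 fold change of Abcg8 was -0.00445, and with both numbered 3 left out the log2 fold change of mt-Atp8 was +0.000886, the log2 fold change of Osgin1 -0.0387 and the log2 fold change of Pfkl -0.0225. Depth is unknown, so whether more reads would change a call cannot be said, and the cause of each change below was not tested.

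The single gene called lower became 0 with a pseudocount of 5, with no filter, with the 5 TPM filter, which removes Gm13597, under quantile normalization, under the replicate block alone or with median-ratio scaling, and with both libraries numbered 1 or 3 left out. With both numbered 2 left out, 1 gene was called higher. Leaving out 1 library gave 0 to 2 genes higher and 0 to 1 lower. Genes with an unadjusted p below 0.05 numbered 773 with no filter, when 23500 genes were tested, 197 with the 5 TPM filter, 707 under the replicate block and 237 without the libraries numbered 2.

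The count of lists called higher was 4 under quantile normalization, 5 under the replicate block, 6 under that block with median-ratio scaling, 0 with an estimated correlation, 4 without the libraries numbered 1, 1 without those numbered 3, and 2 to 5 with 1 library left out. The count called lower was 4 with no filter, 3 under quantile normalization, 5 without the abundant and mitochondrial genes, 0 with an estimated correlation, 5 and 3 without the libraries numbered 2 and 3, and 3 to 13 with 1 library left out. The replicate block added the acute phase, MHC class II and ER stress lists, at 0.0472, 0.0114 and 0.0133, and changed no other call on a list. Median-ratio scaling added nuclear oxidative phosphorylation genes as lower (0.00924) and immediate early genes as higher (0.0474), quantile normalization added the acute phase list (0.00511) and secreted hepatocyte proteins (0.00226) as higher, no filter added cell cycle genes as lower (0.00812), and the 5 TPM filter added gluconeogenesis as lower (0.0257). Leaving out 1 library added 0 to 7 lists, and leaving out both of 1 number 0 to 6.

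The calls on cholesterol synthesis and pericentral genes held in 21 of 22 alternatives each, and all 11 calls were lost with an estimated correlation (adjusted p = 0.902 each). The other adjusted p values of lost calls follow. With no filter, bile acid and male-biased genes were at 0.343, glycolysis and xenobiotic genes at 0.273, NRF2 genes at 0.171 and mitochondrially encoded genes at 0.216. Under median-ratio scaling, bile acid genes were at 0.0621, glycolysis at 0.0697, xenobiotic at 0.0529, male-biased at 0.664 and ribosomal protein genes at 0.109. Under quantile normalization, bile acid genes were at 0.221, glycolysis at 0.175, NRF2 at 0.0969, xenobiotic at 0.168, male-biased at 0.926 and mitochondrially encoded genes at 0.733. Without the abundant and mitochondrial genes, bile acid and glycolysis genes were at 0.0599 and male-biased genes at 0.318. With library weights, bile acid genes were at 0.0755, glycolysis at 0.0581 and male-biased at 0.161. Male-biased genes were at 0.0558 with a pseudocount of 0.1, 0.0535 with no variance trend and 0.156 under the replicate block with median-ratio scaling, where ribosomal protein genes were at 0.0852.

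Without the libraries numbered 1, bile acid genes were at 0.0736 and male-biased at 0.572. Without those numbered 2, glycolysis was at 0.170, NRF2 at 0.482, stellate and fibrosis genes at 0.190, xenobiotic at 0.651, mitochondrially encoded at 0.541 and ribosomal protein genes at 0.156. Without those numbered 3, fatty acid synthesis was at 0.109, bile acid at 0.453, glycolysis at 0.666, stellate and fibrosis at 0.0590, xenobiotic at 0.194, male-biased at 0.123 and mitochondrially encoded at 0.420. With 1 library left out, adjusted p ranged from 7.7e-11 to 0.501 for fatty acid synthesis, 0.00517 to 0.247 for bile acid, 0.00492 to 0.857 for glycolysis, 2.0e-06 to 0.397 for NRF2, 0.00190 to 0.248 for stellate and fibrosis genes, 2.6e-05 to 0.958 for xenobiotic, 1.6e-12 to 0.981 for male-biased and 3.0e-07 to 0.337 for mitochondrially encoded genes. The direction of the male-biased call turned without WT replicate 3 (0.0373), KO replicate 1 (0.913) and KO replicate 2 (0.981), and that of glycolysis without KO replicate 3 (0.857).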

Other observations

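The tests of sequence identity, chromosome, sex-linked genes and endothelial markers were chosen or had their bounds set only after the values were seen; the others were set before. The bound for Xist in particular was first set at exactly 0 and was reset to 0.1 TPM once its highest value, 0.005 TPM, was seen.

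The first principal component of these livers ran with the replicate number and not with the genotype label. This component took 38.2% of the variance and placed both libraries numbered 3 at one end (18.9 for WT, 33.1 for KO) and both numbered 2 at the other (-19.5 and -19.0). The next component (20.1%) put WT replicate 3 at 10.8 and KO replicate 3 at -14.3. The other same-numbered libraries shared a sign on it, at 11.7 (WT) and 17.7 (KO) for number 1 and -5.33 and -20.5 for number 2. Selenbp2, a male-biased gene, was at 903 and 1048 TPM in the libraries numbered 3 and at 38.1 and 196.7 in those numbered 2, with 197.4 and 68.0 in those numbered 1. Moxd1, also male-biased, was at 11.5 and 47.5 TPM in the libraries numbered 3 and listed at 0 in those numbered 2, with 0.1 and 1.26 in those numbered 1. The desaturase gene Scd1 was at 5413 and 3296 TPM in the libraries numbered 2, 1406 and 181 in those numbered 3, and 525 and 1332 in those numbered 1. Cfd, the adipsin gene, was at 23.2 and 22.3 TPM in the libraries numbered 1 and at no more than 2.47 in the other 4.

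KO replicate 3 had the highest values of Socs2 and Cish. Socs2 was at 55.7 TPM there against 1.99 to 13.4 in the other 5 libraries, and Cish at 24.7 against 2.83 to 10.3. Both are feedback inhibitors induced through STAT5. These genes were chosen after their values were seen and no test was run on them.

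For the differences that follow the replicate number, a mix of male and female livers is argued against by the Y-linked genes Ddx3y and Eif2s3y, which were at 18.5 TPM or more in every library, with Xist at 0.005 TPM or less. For male-biased genes other than Mup, the difference between libraries numbered 3 and 2 was 1.52 (WT) and 1.32 (KO) on the log2 scale, and recomputing TPM without the abundant genes kept at least 1.09 times its value. The 20 most abundant genes took 42.2% and 46.8% of TPM in WT replicates 2 and 3, and 40.7% and 43.2% in KO replicates 2 and 3. With shares this close, their removal could not have taken the difference away. The shares, more than the recomputed values, therefore argue against a scale set by a few abundant transcripts, for these genes. The time of day of sampling stays open: over 28 clock genes this difference correlated at 0.779 between the labels, above the median of 0.505 of 10000 random lists matched on expression but below their 95th percentile of 0.821, a correlation across genes, which are not independent replicates. A shared litter, cage or day is not in the labels and was not tested. Beyond sex and time of day no biological explanation was tested, and the genotype label crosses the numbers. The libraries numbered 3 had the fewest genes at 1 TPM or more within each label (11013 for WT, 11328 for KO). They also had the lowest library weights (0.69 and 0.59), and whether sample quality differed by number was not tested.

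The absence of Gm13597 from the 3 libraries labelled KO may reflect how reads were divided between identical copies. Its transcript matches Tax1bp3 over 100% of its bases. A similar pseudogene, Gm14117, matches Atpaf1 over all of its 843 bases. Other tested pseudogenes were not matched, so these matches show only that reads could be shared. Tax1bp3 was at 13.939, 9.953 and 7.988 TPM in the libraries labelled WT and at 12.677, 10.011 and 7.536 in those labelled KO. Tax1bp3 thus showed no rise in the libraries labelled KO, but it varied within each label, so its values do not decide how reads were divided. Over the 10 ways to split the 6 libraries into 3 and 3, 34 genes were listed at 0 in one side and at 1 TPM or more in all of the other, and 44.8% of the 29 with an annotated type were pseudogenes, against 1.98% of tested genes. The tested genes were not matched to these on expression, and Gm13597 is itself 1 of the 34, so this excess cannot tell read sharing from low expression. The real split held 1 such gene and each other split 2 to 6. A segment carried along with the targeted locus is argued against because Gm13597 lies on chromosome 2 and Epas1 on chromosome 17; an effect of genotype on the pseudogene itself stays open.

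That Epas1 was not lower in the libraries labelled KO has 2 candidate explanations that these values leave open. Loss of 1 exon could leave the gene-level TPM nearly as it was, since the largest internal exon holds 9.17% of the transcript, but the deleted exon is not in the labels and TPM per exon was not analysed here. The outcome set beforehand for this was met, but the opposite outcome could not occur in a transcript of this many exons, so it decides nothing. RNA of endothelial cells, which keep the gene, could hide a fall in hepatocytes. Epas1 exceeded the mean difference of 22 endothelial markers by 0.23 on the log2 scale, within 2 standard errors of the Epas1 difference alone. Those markers overlapped between the labels (the most abundant, Clec4g, was at 51.3 ± 2.47 and 50.96 ± 1.85 TPM). Their mean difference of +0.12 was near the median of all genes (+0.09) and was +0.008 under median-ratio scaling, so they showed no rise beyond that of all genes. A wrong genotype label was not tested and also stays open.

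For a chromosome segment carried along with the targeted locus, of 58 tested genes within 10 Mb, 0 had an unadjusted limma p below 0.05, against 3.09% of 11163 others (Fisher's exact p = 0.426, two-sided, 95% interval of the odds ratio from 0 to 2.07). An odds ratio of 1 or lower, set beforehand as evidence against such a segment, was met. Even with 0 of 58 genes the interval reached 2.07, so this test could not have argued against a segment beyond its spread, and it leaves this open.

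With 10 splits of the 6 libraries, no share under 0.05 can be reached, so chance could not be argued against here. The outcome set beforehand for chance, a share of at least 0.05, was met for all 3 results below but could not have failed, so it decides nothing. The real split gave 1 gene past the threshold, 360 with an unadjusted p below 0.05 and 11 called lists, and 7, 8 and 7 of the 10 splits gave as many; the highest other values were 3, 1228 and 18. The 3 other splits that part all 3 same-numbered pairs gave 0 genes, 161 to 483 unadjusted and 4 to 18 lists. The 6 splits, which keep 2 pairs together, gave up to 3 genes, 466 to 1228 unadjusted and 8 to 18 lists, and the split of WT replicates 1 and 3 with KO replicate 3 from the rest gave the 1228 unadjusted, which points to a structure of the samples. The count of lists does not separate these kinds of split, since both reach 18.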
